A study of Homo sapiens with 24 samples.

How the data were processed

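The series measured labelled RNA in U2OS cells (U2O2 in the source labels), an established human osteosarcoma line, made to express Tob2 or to carry an empty vector under a Tet-off promoter, which is silent with doxycycline and active without it. RNA made during a bromouridine pulse was followed through a chase by immunoprecipitating bromouridine-containing cytoplasmic RNA and sequencing it. The 24 libraries formed 4 arms (vector line and Tob2 line, each uninduced and induced), with 1 library per arm at each of 6 chase times (0, 0.5, 1, 2, 4 and 6 h). The labels gave no repeated library at any time point and no information on separate cultures, so every p-value below measures spread between these libraries only.

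The deposited values were TPM, a length-corrected share of a fixed library total, for 48009 RefSeq transcript rows, scaled by the authors so that every library had the same total, and printed with 2 decimals. The submitters' processing notes named Trim Galore, Bowtie2, RSEM 1.3.0 and the genome build hg19 without stating their roles. No spike-in rows were present, so the total amount of labelled RNA in a library was not kept and a slope is a change relative to all labelled RNA. Read depth was not given and cannot be recovered from TPM, so no counting interval is reported. Coordinates were left out because the annotation at hand was for another genome build. Of the rows, 5 had no gene symbol, and 74 carried symbols that had been turned into dates, of which 72 were restored through their accession.

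TPM were summed per gene symbol (25342 genes) and analysed as log2(TPM + 1) for the 13276 genes with a mean of at least 1 TPM over the 24 libraries. For each gene, limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a mean-variance trend) fitted a level and a straight chase slope in each arm, with time centred at 2.25 h, leaving 16 residual degrees of freedom. The spread was therefore the deviation from straight lines on the log2 scale, pooled over the arms. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. The comparisons were the slope within each arm, and for both slope and mean level the Tob2 line induced against uninduced, the vector line induced against uninduced, the difference between these effects, and the uninduced lines against each other. Chase time was a design variable shared by the arms, and residuals of libraries of different arms at the same time correlated (median r of 0.276 over 36 pairs, from 0.0498 to 0.503, 29 of them above 0.1). Each contrast between arms was also fitted with chase time as a block (12 residual degrees of freedom), and its value is printed where it changed a call or a count by more than 1.5 times.

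The TOB2 level was tested with an exact two-sided sign-flip permutation test over the 6 chase times (64 flips), and the spread of slopes over genes with an exact two-sided permutation test over the 64 swaps of induced and uninduced labels within chase times. With 6 pairs the smallest p that either test can give is 0.03125. Of 30 gene lists fixed beforehand, 28 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, beside an estimated correlation and limma's fry, with Benjamini-Hochberg adjustment over the lists within a comparison. Lists of mitochondrially encoded genes and of blood cell markers had fewer than 5 tested members and gave no test.

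Genes were named by a rule: for each comparison, the 10 largest positive and 10 largest negative coefficients among genes that passed, had a mean of at least 5 TPM and kept their sign in all fits that left out 1 chase time, or the 5 smallest p-values of a direction in which fewer than 5 passed. Slopes within an arm were described in vector uninduced cells by the same rule, with values in the other arms. The rule also took up to 4 members of each list with the largest coefficients and a fixed set of genes of the TOB and BTG family, deadenylases, MYC, CCND1 and CDKN1A. Some genes that the rule takes are not reported here. Lists, comparisons, tests, this rule and the alternatives of the next paragraph, apart from the last named, were set before the data were examined.

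The alternatives were a pseudocount of 0.1, no filter on low values (20007 genes), centring of each library on its median or on the mean of a list of stable reference genes, and TPM rescaled without histone and small noncoding RNAs (2144 genes left out, 13394 tested). Mitochondrially encoded RNAs were to be left out of the rescaled TPM too, but 0 members of that list were present. Further ones were only the libraries of the arms compared, only 0 to 2 h, each chase time left out in turn, single transcripts (21466) in place of gene sums, and chase time as a block. Leaving out the Tob2 induced 0.5 h library was added after the data were seen. The pipeline was tested on simulated data, in which known changes were added to 200 genes. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.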

Results

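Bromouridine-labelled cytoplasmic RNA was sequenced from U2OS cells of a vector line and a Tob2 line, each without and with induction, at 6 chase times from 0 to 6 h (24 libraries, 1 per arm and time). Tob2 is a member of the TOB and BTG family, which recruits the CCR4-NOT deadenylase to mRNA, and the series asked whether its induction speeds the turnover of mRNA across the transcriptome. The number of genes at 1 TPM or more ranged from 12441 to 13666 per library, and read depth was unknown. Small noncoding RNAs were abundant early: RMRP, the RNA of RNase MRP, took 14.05%, 11.44%, 12.39% and 9.28% of TPM at 0 h in vector uninduced, vector induced, Tob2 uninduced and Tob2 induced cells, and 3.32%, 2.27%, 2.51% and 1.88% at 6 h. The 10 most abundant genes together took 29.25%, 27.06%, 27.78% and 22.42% at 0 h in the same order of arms, and 12.87%, 9.97%, 11.2% and 9.72% at 6 h. No arm had a repeated library at any time, so errors below are deviations from straight lines unless stated otherwise.

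TOB2 was higher in Tob2 induced than uninduced cells at 6 of 6 chase times. Its mean was 438 ± 19.6 TPM (SD, n = 6 chase times) after induction and 181 ± 55.6 TPM without, and the mean log2(TPM + 1) difference was 1.35 ± 0.55 (SD, n = 6; exact sign-flip permutation test, p = 0.03125, the smallest this test can give). On that scale, with 1 added to TPM, the geometric mean ratio was 2.55, with 1.91 at 0 h and 5.28 at 6 h. In the vector line TOB2 was 161 TPM in induced and 175 TPM in uninduced cells, a log2 difference of −0.13 (exact p = 0.0625). Labelled TOB2 fell over the chase in vector uninduced cells by 0.22 log2 per h and kept 432 of 445 TPM between 0 and 6 h in Tob2 induced cells, where its slope of −0.01 ± 0.04 log2 per h did not pass. TOB1, the close relative of TOB2, fell by 0.19 log2 per h in vector uninduced cells. Over 0 to 2 h alone the slopes of TOB1 (0.10) and TOB2 (0.01) in vector uninduced cells were not below 0.

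**Figure D1:**
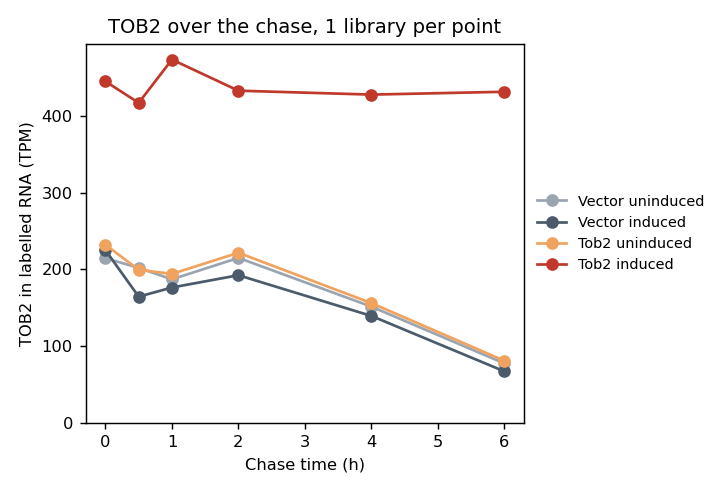
TOB2 in labelled RNA (TPM, vertical axis from 0) against chase time in h for the 4 arms, 1 library per point. The Tob2 induced arm starts at 445 TPM and ends at 432 TPM, above the other 3 arms at every time.

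Within each arm, the comparison asked which labelled RNAs were lost or kept relative to the whole. Immediate-early transcription factor RNAs were lost fastest among the mRNAs named in vector uninduced cells: JUNB went from 1529 to 20.8 TPM in 6 h, a slope of −1.06 ± 0.03 log2 per h (limma, adjusted p = 2.0e-14). EGR1 had −1.15 ± 0.13, IER5 −0.95 ± 0.05, the cell cycle regulator SERTAD1 −0.92 ± 0.04 and JUN −0.91 ± 0.08. In the other 3 arms JUNB had slopes of −1.08, −1.08 and −1.18, and EGR1 −1.13, −1.01 and −1.01. BTG2, an antiproliferative member of the same family as Tob2, fell by 0.69 and MYC by 0.45 log2 per h, and the CDK inhibitor CDKN1A by 0.22. At the other end were ZBED6 (0.44 ± 0.05), which went from 29.5 to 157 TPM, and TMED7 (0.41 ± 0.09). They were followed by the RNA polymerase II subunit POLR2B (0.40 ± 0.05), UBP1 (0.39 ± 0.06), the ubiquitin ligase subunit SKP2 (0.39 ± 0.04) and BCLAF1 (0.38 ± 0.08). These 6 genes passed in all 6 fits that left out 1 chase time. The short RNAs MIR6126 (0.79 ± 0.29), SNORD94 (0.61 ± 0.24) and LOC103021295 (0.65 ± 0.25) passed with wide errors in 4, 3 and 3 of those fits. Among falling short RNAs, SNAR-A1 and SNAR-A2 had identical values (−1.57 ± 0.51, passing in 3 of 6 fits), MIR6077 had −1.09 ± 0.35, SNORA29 −0.90 ± 0.18 and SNORD83A −0.88 ± 0.23.

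Over all 13276 genes, 7469 slopes passed in vector uninduced cells (5025 higher, 2444 lower), 7787 in vector induced (5722 and 2065), 7573 in Tob2 uninduced (4875 and 2698) and 7294 in Tob2 induced cells (4505 and 2789). In all 4 arms 1647 genes fell and 3950 rose, and 6 passed in opposite directions in different arms. Slopes correlated between arms across genes, which are not independent replicates, with r from 0.891 to 0.912. The balance of rising and falling genes depended on the reference: centring each library on stable reference genes moved the median of all slopes in vector uninduced cells by −0.13 log2 per h, after which 987 genes rose and 6201 fell, and rescaling TPM without histone and small noncoding RNAs gave 2408 and 4165. The chase window mattered as well, with 2332 slopes passing over 0 to 2 h alone in vector uninduced cells (2079 higher, 253 lower).

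Replication-dependent histone RNAs, which end in a stem-loop in place of a poly(A) tail, fell in vector uninduced cells for 59 of 62 tested members (60 adjusted over the list alone), with a median of −0.28 log2 per h. The list lay below the other genes (limma camera, adjusted p = 3.3e-39, adjusted p = 0.056 with an estimated correlation). HIST4H4 had −0.46, HIST1H2BJ −0.45, HIST1H2BM −0.44 and HIST1H2AK −0.43 log2 per h. In the other arms 61, 60 and 58 histone genes fell. Of 41 immediate-early and AU-rich-element genes, 30 fell and 1 rose (32 and 1 adjusted over the list alone, camera adjusted p = 2.2e-15, adjusted p = 0.15 with an estimated correlation). Of 363 ZNF zinc finger genes, 204 fell and 23 rose (camera adjusted p = 5.0e-21, adjusted p = 0.11 with an estimated correlation), among them ZNF574 (−0.63), ZNF830 (−0.56), ZNF581 (−0.52) and ZNF16 (−0.51). The 285 small noncoding RNAs were also below the other genes, with 55 falling and 7 rising (camera adjusted p = 7.5e-07, adjusted p = 0.11 with an estimated correlation). Among 23 p53 targets 11 fell and 6 rose (camera adjusted p = 0.0014, adjusted p = 0.18 with an estimated correlation), with BBC3 at −0.43 and AEN at −0.33. Of 15 CDK inhibitors and antiproliferative genes, 7 fell and 3 rose (camera adjusted p = 0.0029, adjusted p = 0.27 with an estimated correlation), with GADD45B at −0.46 and CDKN1B at −0.48, though CDKN1B had 0.13 over 0 to 2 h. Of 18 TGF-beta and SMAD targets, 9 fell and 1 rose (camera adjusted p = 0.0029, adjusted p = 0.28 with an estimated correlation), with ID1 at −0.65 and TGIF1 at −0.64. The medians of these 7 lists stayed below 0 under each scaling that kept their genes.

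RNAs of basic cell machinery lay above the other genes in vector uninduced cells. In 4 lists the median stayed above 0 under each scaling, but fewer members rose with stable reference centring. There 11 of 35 proteasome genes rose and 1 fell, and 16 of 32 translation factors rose and 4 fell. Of 56 spliceosome genes 15 rose and 7 fell, and of 31 G2/M genes 12 rose and 1 fell. The counts that follow are without that centring. Proteasome subunit RNAs rose for 34 of 35 members and fell for 1 (camera adjusted p = 2.1e-09, adjusted p = 0.15 with an estimated correlation), with PSMD11 at 0.28. Translation factors rose for 29 of 32 (camera adjusted p = 1.1e-07, adjusted p = 0.27 with an estimated correlation), with EIF4B at 0.36. Spliceosome and hnRNP genes rose for 46 of 56 and fell for 1 (camera adjusted p = 2.1e-07, adjusted p = 0.32 with an estimated correlation), with U2AF2 at 0.37. G2/M genes rose for 26 of 31 (camera adjusted p = 1.9e-06, adjusted p = 0.28 with an estimated correlation), with TPX2 at 0.33. Stable reference genes rose for 22 of 23 and fell for 1 (camera adjusted p = 8.1e-06, adjusted p = 0.27 with an estimated correlation), with PKM at 0.22, and their median stayed above 0 with median centring and rescaling, their own centring being no test of them. In 8 further lists the median was above 0 but flipped to below 0 with stable reference centring. Cytosolic ribosomal protein genes rose for 73 of 83 members and fell for 2 (camera adjusted p = 2.8e-11, median −0.02 after centring). Nuclear genes of oxidative phosphorylation rose for 62 of 75 (camera adjusted p = 1.3e-08, median −0.01 after centring). Mitochondrial ribosomal proteins rose for 52 of 77 and fell for 1 (camera adjusted p = 8.1e-06, median −0.03 after centring). G1/S and DNA replication genes rose for 21 of 35 and fell for 1 (camera adjusted p = 0.0025, median −0.03 after centring). Cholesterol synthesis genes rose for 14 of 22 and fell for 1 (camera adjusted p = 0.0087, median −0.00074 after centring). Decapping, exosome and nonsense-mediated decay genes rose for 22 of 39 and fell for 1 (camera adjusted p = 0.0095, median −0.03 after centring). Autophagy and lysosome genes rose for 12 of 18 and fell for 1 (camera adjusted p = 0.016, median −0.01 after centring). Extracellular matrix genes rose for 15 of 21 (camera adjusted p = 0.019, median −0.03 after centring). None of these 8 calls held with an estimated correlation, where the smallest adjusted p was 0.15 for oxidative phosphorylation.

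Of the 23 CCR4-NOT and deadenylation genes, the machinery with which Tob2 works, 15 rose and 4 fell in vector uninduced cells. With stable reference centring 3 rose and 7 fell, and after rescaling 6 rose and 5 fell. The list as a whole did not differ from other genes (camera adjusted p = 0.24). CNOT1, the scaffold of the complex, had 0.34 ± 0.05 log2 per h and went from 38.8 to 146 TPM, and the deadenylase CNOT7 had 0.26 ± 0.04. CNOT6 (0.15), CNOT6L (0.10), CNOT8 (0.17) and PAN3 (0.10) rose less and PAN2 (−0.09) fell, but CNOT6L (−0.03) and PAN3 (−0.03) reversed with stable reference centring. CNOT6L, CNOT8 and PAN2 passed in 2, 3 and 2 of the 6 fits that left out 1 chase time. BTG1 (−0.17, adjusted p = 0.093) and CCND1 (0.00062, adjusted p = 0.99) did not pass, but BTG1 rose over 0 to 2 h (0.44, adjusted p = 0.018) and CCND1 fell with stable reference centring (−0.13, adjusted p = 1.3e-04) and after rescaling (−0.08, adjusted p = 0.0049). The lists of ATF4 and unfolded protein response genes (12 rose, 7 fell), heat shock genes (7 and 5), hypoxia and glycolysis genes (9 and 3), interferon-stimulated genes (4 and 4), the microRNA machinery (7 and 1), epithelial markers (3 and 0) and snoRNA host genes (3 and 6) did not differ from other genes by camera. CHAC1 (−0.75), a target of ATF4, and the chaperone genes HSPA1B (−0.39), DNAJB1 (−0.37) and HSPA1A (−0.36) were among their falling members. With stable reference centring more members fell than rose in each of these lists. In the order given, the rising and falling counts were then 3 and 11, 2 and 6, 1 and 6, 0 and 11, 0 and 4, 0 and 2, and 0 and 13.

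Whether Tob2 induction changed the relative loss of any RNA was asked by the difference in slope between Tob2 induced and uninduced cells. TOB2 itself came closest among rising genes: its slope was higher by 0.21 ± 0.06 log2 per h after induction, which did not pass (adjusted p = 1.00, adjusted p = 0.033 with chase time as a block). Other genes with small p-values were PPA2 (0.11 ± 0.04), DCXR (0.12 ± 0.04) and TRAPPC2 (0.10 ± 0.04) above 0, and SPSB2 (−0.23 ± 0.05), CBY1 (−0.24 ± 0.07), SNORD83B (−0.47 ± 0.13), HDDC3 (−0.16 ± 0.04) and RNF146 (−0.10 ± 0.03) below 0. None of them passed. MYC (−0.06 ± 0.04), TOB1 (−0.07 ± 0.05), BTG2 (−0.06 ± 0.06), CNOT1 (−0.01 ± 0.06) and CCND1 (−0.03 ± 0.04) did not pass in either fit. No gene passed in limma, where 302 had an unadjusted p under 0.05, below the 664 of a calibrated test. Deviations that the arms share at a chase time enter the error of this fit, so the shortfall is no evidence of unchanged slopes. The median error was 0.052 log2 per h, and 0.036 with chase time as a block. With the block 17 genes passed (1 higher, 16 lower, 1125 with an unadjusted p under 0.05). On simulated data this comparison recovered 0% of slope differences of 0.1 log2 per h, 28.5% of 0.2 and 86.5% of 0.4, and the block fit recovered 10%, 68% and 94%.

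**Figure D2:**
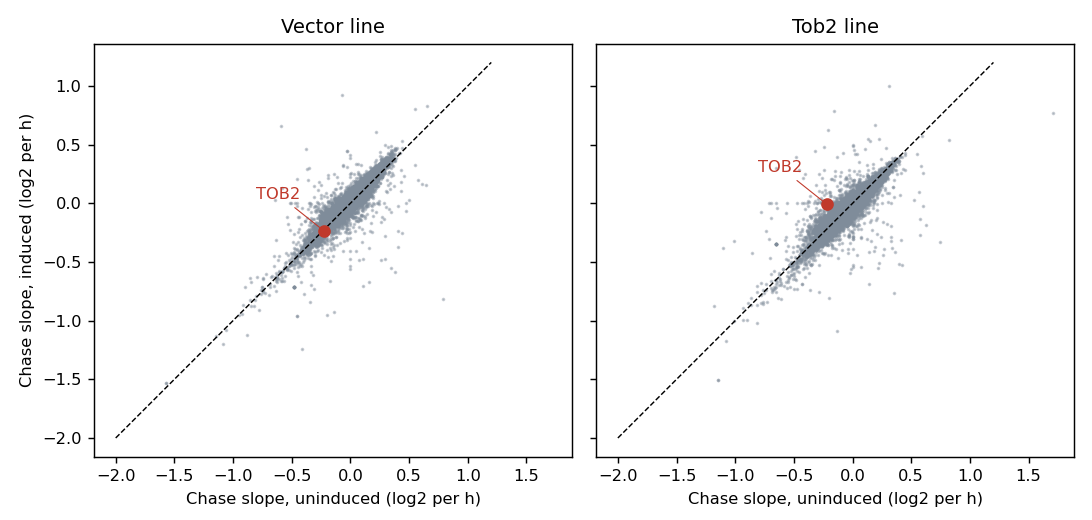
Chase slope (log2 per h) of each of 13276 genes in induced (vertical axis) against uninduced cells (horizontal axis), for the vector line and the Tob2 line; the dashed line marks equal slopes. TOB2, in red, lies at −0.22 and −0.24 in the vector line and at −0.22 and −0.01 in the Tob2 line.

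Small noncoding RNAs (median difference 0.05 log2 per h, camera adjusted p = 0.0029) and snoRNA host genes (median 0.02, adjusted p = 0.0071) lay above other genes in this slope comparison. Extracellular matrix genes (median −0.04, adjusted p = 0.046) and immediate-early genes (median −0.04, adjusted p = 0.046) lay below. In each of these lists 0 members passed, and the medians kept their sign under each scaling, but small noncoding RNAs lost their call with median centring (adjusted p = 0.11). All 4 had an adjusted p = 0.99 with an estimated correlation. With chase time as a block, TGF-beta and SMAD targets (adjusted p = 8.2e-04), with ID3 at −0.23 (adjusted p = 0.011), took the place of extracellular matrix genes (adjusted p = 0.10); without the block their adjusted p was 0.99 with an estimated correlation. A factor common to all slopes would widen their spread over genes. Their SD was 0.164 log2 per h in induced and 0.167 in uninduced cells, a ratio of 0.986 (exact permutation test, p = 0.75), and 1.045 in the vector line (exact p = 0.53). Simulated factors of 1.25, 1.5 and 2 on the slopes themselves gave ratios of 1.21, 1.45 and 1.94 (exact p = 0.03125 for each).

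In the vector line, which had doxycycline withdrawn without gaining Tob2, the genes with the smallest slope p-values were RNU4ATAC (−0.78 ± 0.16), MIR6126 (−1.60 ± 0.41) and HIST1H3F (−0.10 ± 0.03) below 0, and SSB (0.12 ± 0.03), LARP7 (0.13 ± 0.04) and HOXB-AS3 (0.26 ± 0.08) above. None passed in limma (283 had an unadjusted p under 0.05; with chase time as a block none passed and 1118 had one). Histone RNAs lay below other genes after doxycycline withdrawal (median −0.06 log2 per h, 0 members passing, camera adjusted p = 1.8e-45, adjusted p = 0.031 with an estimated correlation; 26 fell adjusted over the list alone with chase time as a block). Also below, by camera, were cytosolic ribosomal proteins (median −0.02, adjusted p = 1.8e-17), small noncoding RNAs (median −0.02, adjusted p = 3.3e-07) and oxidative phosphorylation genes (median −0.01, adjusted p = 1.1e-05). Immediate-early genes (median −0.02, adjusted p = 6.9e-04) and TGF-beta and SMAD targets (median −0.02, adjusted p = 0.021) were below as well. Heat shock genes (median 0.07, adjusted p = 1.8e-05) and G1/S genes (median 0.04, adjusted p = 0.011) were above. Mitochondrial ribosomal protein genes were also below other genes (adjusted p = 0.010), though their median was 0.0031 and flipped to below 0 under each other scaling. With an estimated correlation none of these other 8 passed, the smallest being adjusted p = 0.072 for small noncoding RNAs. With median centring small noncoding RNAs and TGF-beta and SMAD targets lost their calls (adjusted p = 0.099 for both), and with chase time as a block spliceosome genes were above other genes (adjusted p = 0.0035, adjusted p = 0.99 with an estimated correlation and no block).

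The difference between the slope effects of the lines, the test of whether the Tob2 line responded unlike the vector line, was largest by p-value for RNU4ATAC (1.22 ± 0.22, adjusted p = 0.30) and included the heat shock genes HSPA1B (−0.24 ± 0.07) and HSPA1A (−0.20 ± 0.07), SDCCAG8 (−0.24 ± 0.07), RNF146 (−0.14 ± 0.04) and MAGI1 (−0.15 ± 0.05), none of which passed. In limma 0 genes passed (251 with an unadjusted p under 0.05), and with chase time as a block 1 passed, FBXO45, a name taken after its value was seen. On simulated data this comparison recovered 0% of slope differences of 0.1 and of 0.2 log2 per h and 74% of 0.4 (0%, 44.5% and 87% as a block). Histone RNAs lay above other genes (median 0.07, camera adjusted p = 2.8e-30, adjusted p = 0.073 with an estimated correlation), and so did small noncoding RNAs (median 0.04, adjusted p = 7.3e-11, adjusted p = 0.026 with an estimated correlation). For histone RNAs this came mainly from the vector line, where the median slope difference on induction was −0.06, against −0.00015 in the Tob2 line. Ribosomal proteins (median 0.01, adjusted p = 1.4e-10, adjusted p = 0.87 with an estimated correlation) and oxidative phosphorylation genes (median 0.0047, adjusted p = 3.1e-05, adjusted p = 0.65 with an estimated correlation) were above as well. The same held for snoRNA host genes (median 0.01, adjusted p = 0.0041, adjusted p = 0.87 with an estimated correlation). Heat shock genes lay below (median −0.07, adjusted p = 1.3e-05, adjusted p = 0.37 with an estimated correlation), and G1/S genes only with chase time as a block (median −0.05, adjusted p = 0.0053, adjusted p = 0.98 with an estimated correlation and no block). The medians of the lists other than G1/S kept their sign under each scaling that kept the genes. Between the uninduced lines PPA2 (−0.18 ± 0.04, adjusted p = 0.87), RNU4ATAC (−0.72 ± 0.16), AARSD1 (−0.15 ± 0.04) and H3F3A (1.56 ± 0.46) had the smallest slope p-values. There 0 genes passed in limma (160 with an unadjusted p under 0.05; with chase time as a block 0 passed and 393 had one). Histone RNAs (median −0.04, camera adjusted p = 8.4e-05), ribosomal proteins (median −0.01, adjusted p = 0.0071) and snoRNA host genes (median −0.03, adjusted p = 0.017) lay below other genes there. Heat shock genes lay above (median 0.02, adjusted p = 0.0071). All 4 had an adjusted p = 0.98 with an estimated correlation and kept the sign of their median under each scaling that kept the genes, but ribosomal proteins lost their call with median centring (adjusted p = 0.17).

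The level of labelled RNA over the chase was compared next, since a pulse also records what is made and exported. In Tob2 induced cells TOB2 was higher by 1.35 ± 0.13 log2 (adjusted p = 6.4e-06), the membrane protease ADAM9 by 0.83 ± 0.08 (48.5 against 27.0 TPM, adjusted p = 8.9e-06), HNRNPA1P33 by 0.77 ± 0.09 and tropomyosin TPM1 by 0.64 ± 0.09. RPPH1, the RNA of RNase P, was lower by −0.72 ± 0.09 (adjusted p = 4.3e-04), the cAMP-responsive factor CREM by −0.49 ± 0.08 and the histone gene HIST1H3F by −0.41 ± 0.06. These 7 genes passed in all 6 fits that left out 1 chase time. Passing in fewer were ALPK2 (0.88, 3 fits), ANXA8L1 (0.82, 5 fits), HOXC-AS1 (0.65, 1 fit), LINC00842 (0.62, 3 fits), SLITRK5 (0.62, 1 fit), HIST2H2AB (−0.47, 5 fits), TERC, the telomerase RNA (−0.46, 1 fit), HIST1H3H (−0.43, 2 fits), LHX2 (−0.43, 0 fits), HIST1H3G (−0.43, 3 fits), HIST1H3A (−0.40, 1 fit) and JUND (−0.39, 2 fits). At the level of single transcripts TPM1 and CREM did not pass. CREM was also higher in Tob2 uninduced than in vector uninduced cells, a difference that did not pass. TOB1 was not shown to differ (−0.27, adjusted p = 0.36, adjusted p = 0.022 with chase time as a block), and MYC (0.05), CCND1 (−0.02) and CDKN1A (0.06) did not pass in either fit.

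In total 122 genes differed in level between Tob2 induced and uninduced cells (99 higher, 23 lower), and 893 with chase time as a block (694 higher, 199 lower), including all 122. The count and its balance moved with the libraries and the scaling used. Leaving out 0.5 h gave 19 genes, 1 h 24, 4 h 34, 2 h 45, 0 h 56 and 6 h 114, and leaving out the Tob2 induced 0.5 h library alone gave 55. Centring on stable reference genes moved the median of all genes by −0.12 log2 and gave 133 genes, of which 22 were higher and 111 lower, with 45 shared with the 122. On simulated data the fit recovered 0% of level differences of 0.25 log2, 48% of 0.5 and 95.5% of 1, and the block fit recovered 30%, 75.5% and 96.5%.

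**Figure D3:**
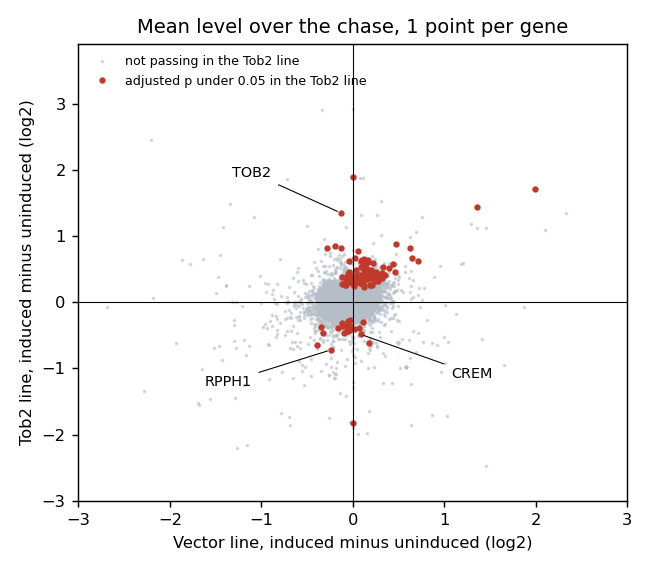
Difference in mean level between induced and uninduced cells (log2) in the Tob2 line (vertical axis) against the vector line (horizontal axis), 1 point per gene, with the 122 genes that passed in the Tob2 line in red; 3 genes lie outside the axes. TOB2 is high on the vertical axis (1.35) and near 0 on the horizontal axis (−0.13), and RPPH1 (−0.72) and CREM (−0.49) are low on the vertical axis.

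For level in the Tob2 line, histone RNAs and small noncoding RNAs were the 2 lists that passed with an estimated correlation. Of 62 replication-dependent histone genes, 10 were lower (26 adjusted over the list alone) and 0 higher, and with chase time as a block 33 were lower (40 adjusted over the list alone). Their median of −0.22 log2 stayed below 0 under both centrings. The list lay below other genes (limma camera, adjusted p = 1.2e-37, adjusted p = 0.033 with an estimated correlation), and against no change, which limma's fry tests, its adjusted p was 0.038. Small noncoding RNAs lay below other genes as well, with 4 of 285 lower and a median of −0.24 (camera adjusted p = 5.4e-13, adjusted p = 0.011 with an estimated correlation). The vector line, which gained no Tob2, had a similar median for small noncoding RNAs, given below, so this shift was not particular to the Tob2 line. Cholesterol synthesis genes lay below with a median of −0.11 (camera adjusted p = 5.2e-08, adjusted p = 0.14 with an estimated correlation). Of 22 members 1 was lower, 3 adjusted over the list alone and 6 with chase time as a block. Of the 22, 16 had their highest mean level in Tob2 uninduced cells. Their lowest was in Tob2 induced cells for 5, in vector uninduced cells for 8 and in vector induced cells for 9. The Tob2 line medians of small noncoding RNAs and cholesterol synthesis genes stayed below 0 under each scaling that kept the genes. ACAT2 passed (−0.36, adjusted p = 0.013; 3 of 6 fits without 1 time), while INSIG1 (−0.56, adjusted p = 0.24, adjusted p = 0.0010 as a block) and MSMO1 (−0.46, adjusted p = 0.34, adjusted p = 9.0e-04 as a block) passed only as a block. Epithelial markers were above other genes (2 of 7 passed, KRT7 at 0.43 and KRT18 at 0.28, camera adjusted p = 0.024, adjusted p = 0.38 with an estimated correlation), with a median above 0 under each scaling. Stable reference genes were above other genes (camera adjusted p = 0.0014), with 2 of 23 higher, PKM at 0.41 and ANXA2 at 0.36. Mitochondrial ribosomal proteins (camera adjusted p = 0.023) had 2 of 77 higher, 7 adjusted over the list alone, with MRPS17 at 0.26. Oxidative phosphorylation genes (camera adjusted p = 0.024) had 2 of 75 higher, UQCRFS1 at 0.41 and NDUFS6 at 0.38, and spliceosome genes (camera adjusted p = 0.024) 0 of 56. The medians of the last 3 lists flipped to below 0 with stable reference centring, which is no test of the stable reference genes, and with an estimated correlation the smallest of the 4 was adjusted p = 0.84. With median centring mitochondrial ribosomal proteins and oxidative phosphorylation genes lost their calls (adjusted p = 0.16 for both). With chase time as a block, ATF4 and unfolded protein response genes were also below (adjusted p = 0.0069) and translation factors above (adjusted p = 0.0053) other genes, where without the block both had an adjusted p = 0.95 with an estimated correlation. The autophagy gene GABARAPL1 (0.45, adjusted p = 0.044) and the hypoxia gene NDRG1 (0.39, adjusted p = 0.038) passed in lists that did not, in 1 and 0 of the fits without 1 chase time.

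**Figure D4:**
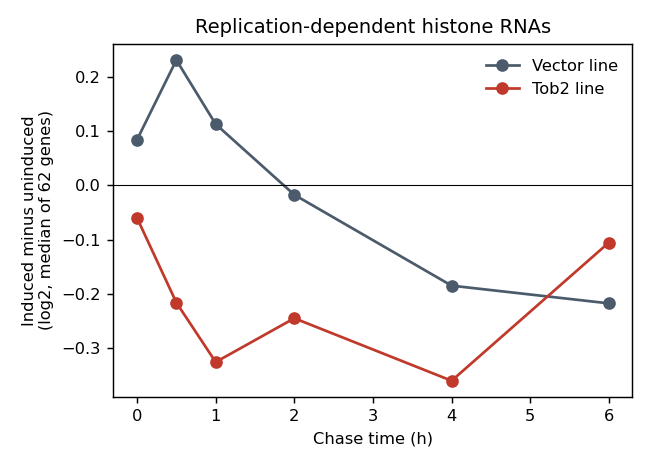
Median difference in log2 level between induced and uninduced cells over 62 replication-dependent histone genes (vertical axis) against chase time in h, for the Tob2 line and the vector line. The Tob2 line is below 0 at 6 of 6 times, from −0.06 to −0.36, and the vector line goes from 0.08 at 0 h to −0.22 at 6 h.

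Doxycycline withdrawal without Tob2 was examined in the vector line. ADAM9 was higher there too, by 0.62 ± 0.08 log2 (41.8 against 25.8 TPM, adjusted p = 0.0011), as was SLITRK5 (0.71 ± 0.12, adjusted p = 0.018). The complement regulator CD55 (0.50 ± 0.08), the lysosomal lipase LIPA (0.45 ± 0.07), ENOX1 (0.44 ± 0.07), RWDD2B (0.43 ± 0.08), OXR1 (0.34 ± 0.06) and USMG5 (0.31 ± 0.06) were also higher. DPH7 (−0.40, adjusted p = 0.072), RRP7B (−0.35), SNORD83B (−1.17), SCARNA2 (−0.35) and RPS9 (−0.19) had the smallest p-values below 0 without passing. ADAM9 passed in all 6 fits that left out 1 chase time, ENOX1 in 4, LIPA in 3, CD55 and SLITRK5 in 2, RWDD2B in 1 and OXR1 and USMG5 in 0. In total 12 genes passed, all higher, and 112 with chase time as a block (67 higher, 45 lower); without 0 h the count was 3. Mitochondrial ribosomal proteins lay above (median 0.05) and small noncoding RNAs below other genes (median −0.25), each with camera adjusted p = 0.013 and adjusted p = 1.00 with an estimated correlation, with 0 members passing and the same sign under each scaling.

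For the difference in level effect between the lines, TOB2 was the gene that passed, at 1.48 ± 0.18 log2 (adjusted p = 0.0012; without 1 h its adjusted p missed 0.05 and 0 genes passed). On simulated data this comparison recovered 0% of differences of 0.25 log2, 5.5% of 0.5 and 81% of 1 (0%, 48.5% and 90.5% as a block), so a low count does not show that the lines responded alike. HNRNPA1P33 (0.71 ± 0.13), NDUFS6 (0.49 ± 0.10), ANXA8L1 (0.95 ± 0.19) and TCEAL4 (0.52 ± 0.11) above 0, and CREM (−0.57 ± 0.11, adjusted p = 0.16), HIST1H3F (−0.42 ± 0.09), PIP5K1B (−0.40 ± 0.09), THAP2 (−0.38 ± 0.10) and ALG9 (−0.37 ± 0.10) below, did not pass. With chase time as a block 40 genes did (29 higher, 11 lower), including CREM (adjusted p = 0.027) and HIST1H3F (adjusted p = 0.041). Histone RNAs were below other genes (median −0.23, camera adjusted p = 1.9e-32, adjusted p = 0.11 with an estimated correlation), with 0 passing and 5 lower adjusted over the list alone. Cholesterol synthesis genes were below too (median −0.16, adjusted p = 2.8e-07, adjusted p = 0.25 with an estimated correlation). So were small noncoding RNAs (median −0.00078, adjusted p = 0.0018, adjusted p = 0.31 with an estimated correlation), whose mean of 0.03 had the opposite sign. Stable reference genes (median 0.14, adjusted p = 0.0077, adjusted p = 0.88 with an estimated correlation) and epithelial markers (median 0.28, adjusted p = 0.010, adjusted p = 0.27 with an estimated correlation) were above, the latter with 3 of 7 higher adjusted over the list alone. These medians kept their sign under each scaling that kept the genes (for stable reference genes under median centring and rescaling, since their own centring sets their mean to 0), and stable reference centring moved the median of all genes by −0.13. With median centring small noncoding RNAs (adjusted p = 0.70) and stable reference genes (adjusted p = 0.18) lost their calls. Translation factors (adjusted p = 0.020), ribosomal proteins (adjusted p = 0.020) and spliceosome genes (adjusted p = 0.027) were above other genes with chase time as a block, and ATF4 and unfolded protein response genes below (adjusted p = 0.037), where without the block each had an adjusted p = 0.92 with an estimated correlation.

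The uninduced lines, compared to see how far the lines differed before induction, differed in 3 genes: H3F3AP4 (8.47 ± 1.34 log2 higher in the Tob2 line), H3F3A (−6.06 ± 0.98) and KLHL13 (0.35 ± 0.06), each with adjusted p = 0.021. H3F3A encodes histone H3.3 and H3F3AP4 is a pseudogene of it, so reads of these genes are hard to tell apart. H3F3A passed in 2 of the 6 fits without 1 time and the other genes in 1, and 4 of these fits gave 0 genes. CREM (0.41, adjusted p = 0.078), ZC3H7A (0.35) and TMEM135 (0.28) above 0 and NDUFS6 (−0.31), RNU4ATAC (−1.41), TCEAL4 (−0.31) and LY6G5C (−0.57) below did not pass. On induction in the Tob2 line CREM was lower and NDUFS6 higher, the opposite of these differences. Their changes on induction can therefore not be told apart from a level particular to Tob2 uninduced cells. With chase time as a block 25 genes passed (22 higher, 3 lower). Cholesterol synthesis genes were above other genes in the Tob2 line (median 0.22, camera adjusted p = 3.0e-07, adjusted p = 0.25 with an estimated correlation), with 7 of 22 passing adjusted over the list alone and 0 over all genes. Their lower level on induction, also in the difference between the lines' effects, can therefore not be told apart from a level particular to Tob2 uninduced cells. Histone RNAs were below (median −0.06, adjusted p = 6.5e-14, adjusted p = 0.41 with an estimated correlation). Both medians kept their sign under each scaling that kept the genes. Ribosomal proteins (1.4e-05), small noncoding RNAs (4.4e-05), oxidative phosphorylation genes (2.0e-04), immediate-early genes (0.0051) and spliceosome genes (0.041) were below other genes, though their own medians were above 0 and flipped to below 0 with median centring, where small noncoding RNAs (adjusted p = 1.00) and immediate-early genes (adjusted p = 0.17) lost their calls and mitochondrial ribosomal proteins (adjusted p = 2.3e-04) and stable reference genes (adjusted p = 0.018) came to lie below. ATF4 and unfolded protein response genes (adjusted p = 9.1e-04) and G1/S genes (adjusted p = 0.0088) were above other genes with chase time as a block and mitochondrial ribosomal proteins below (adjusted p = 0.036), while spliceosome genes lost their call (adjusted p = 0.14). With an estimated correlation their adjusted p was 0.25 for small noncoding RNAs and 0.85 for the others, those gained included.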

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

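Of the tests in this part, those of the share taken by abundant RNAs, of faster histone loss and of fewer replicating cells, and the overlap between lines, were chosen after the results they examine had been seen, and the histone list was singled out from 28 lists after its values were seen.

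TOB2 is reported here because its level changed differently in the lines: the induced minus uninduced difference was 1.48 log2 larger in the Tob2 line than in the vector line, the change that the construct was built to give. The Tob2 induced 6 h library is reported because it stood apart from the other libraries of its arm, with a root mean square deviation from the fitted lines of 0.1863 log2 against 0.2554 to 0.2946 at the other times. Of 24 tests of this kind, 6 measures in each of 4 arms, 1 stood out, and chance gives 1.2. A straight line over these times gives the 6 h point a leverage of 0.69, so the 6 h libraries lay closest to their lines in every arm by design (0.1822 to 0.1925 in the others). Divided by the square root of 1 minus the leverage, the deviation of this library was 0.3345, within the 0.29 to 0.346 of the other times.

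Each count of genes was compared with the counts after swapping arm labels within chase times. For level in the Tob2 line, only the real labels gave as many genes (1 of 32 splits, 122 genes, 3 in the highest other split). With chase time as a block the counts were 893 and 161. The same held in the vector line (1 of 32, 12 and 0, 112 and 3 as a block). It also held between the uninduced lines (1 of 32, 3 and 1, 25 and 1 as a block). A share of 1 in 32 is the smallest this test can give. Each arm was 1 series of libraries, so swaps within chase times cannot exclude a difference in culture or handling of a whole arm. For the difference in level effect between the lines, 5 of 100 drawn splits gave as many genes as the 1 that passed, with 26 in the highest other. Chance was not excluded for that count. With chase time as a block 3 of 100 splits gave as many as 40, but the highest other gave 461. Swapping most labels of 1 line can turn the difference of the effects toward their sum, so these splits are no clean null either. For slope, counts of 0 could not be tested in this way, since every split gives at least 0 genes. They were reached by 32 of 32 splits in the Tob2 line (highest other 12), the vector line (highest other 6) and between the uninduced lines (highest other 0), by 100 of 100 for the difference between the lines (highest other 4), and as a block by 32 of 32 in the vector line (highest other 100) and between the uninduced lines (highest other 0). As a block, the 17 genes in the Tob2 line were matched by 3 of 32 splits (highest other 210) and the 1 gene for the difference by 22 of 100 (highest other 33). Swapping labels at only some chase times can turn a level difference between arms into a slope difference. As a block, levels differed in 893 genes in the Tob2 line. The splits are therefore no clean null for slope, and chance was neither shown nor excluded for these counts.

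The 98 genes called higher in labelled RNA of Tob2 induced cells, TOB2 aside, had a median difference of 0.39 log2 (interquartile range 0.33 to 0.51). If a smaller share of abundant noncoding and histone RNAs were the whole cause, rescaling TPM without them would remove most of it. The median stayed at 0.3361 (0.27 to 0.45), while rescaling moved the median of all genes by −0.06 log2. The share thus accounted for no more than about this shift. So small a shift could hardly remove the median of genes picked for their difference, so this test decides nothing further. Doxycycline withdrawal, which both lines had, stays open for part of the pattern: the same genes had a median of 0.09929 in the vector line (76 of 98 above 0; exact permutation test over 64 swaps, p = 0.03125, the smallest possible), a ratio at the edge of the bound set beforehand. In 6 genes, among them ADAM9 and SLITRK5, both lines passed in the same direction. Independent calls would give 0.089 such genes (33 against 3.50 with chase time as a block). The lines share no library, but both comparisons used 1 variance per gene pooled over all 24 libraries. Genes with a small variance can therefore pass in both, and these expected counts are not a valid level of chance. Withdrawal itself may raise these 6 genes. An effect of Tob2 on transcription or export of the remaining genes stays open and was not tested. A difference in culture or handling of a whole arm, or a level particular to Tob2 uninduced cells, stays open as well.

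The median of 62 replication-dependent histone RNAs was −0.22 log2 in Tob2 induced against uninduced cells. Variation shared by these genes that turned from one chase time to the next would give such a median under many label swaps. Of the 64 swaps, 0 other than the real one and its mirror reached it (exact p = 0.03125, the smallest possible). The median was below 0 at every chase time, so this p was close to fixed. Swaps cannot see variation shared by all libraries of an arm, which stays open. In the vector line the median was −0.01 (exact p = 0.91). Faster loss during the chase as the whole cause needs a slope difference of −0.10 log2 per h; the median of −0.00015 lay further from that than the largest swap reached (0.07), but without 6 h it was −0.05 against −0.15 needed (largest swap 0.15), which leaves this open. Fewer cells replicating DNA would lower G1/S and DNA replication genes too; their median was 0.04518, with 13 of 35 below 0, which leaves this open. A lower synthesis of histone RNA in Tob2 induced cells may contribute, as a hypothesis from the same data that was not tested. The median difference was −0.06, −0.22, −0.33, −0.24, −0.36 and −0.11 from 0 to 6 h, closest to 0 at 0 h, when the chase began.

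The absence of genes with a changed slope in the Tob2 line could hide 1 factor on all decay rates, since TPM fix each library's total. A factor above 1 would make the slope difference grow with a gene's own slope in vector cells, but the coefficient was −0.02467 (exact p = 0.66; largest swap 0.08), and 0.04 in the vector line (exact p = 0.47), so neither a gain nor a loss was shown. The ratio of the spreads of 0.986 stayed below the 1.21 that a simulated factor of 1.25 gave. Swaps of the real labels reached a ratio of at most 1.091. These values argue against a common factor of 1.25 or more on the straight slopes measured here, since the simulation multiplied whole slopes. A factor on decay alone would not scale any part of a slope that comes from making or export of RNA, so its size stays open. A smaller factor on the slopes stays open too, since the coefficient lay within the range of the swaps on both sides of 0.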

How the results depend on the processing

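Leaving out the Tob2 induced 0.5 h library was chosen after the data were seen, as was the choice to follow list members' slopes across alternatives in vector uninduced cells only, made after some of them had reversed in the other 3 arms. The values left out in this way held 23 further reversals, all over 0 to 2 h. Of 232 values compared for counts, lists, TOB2 and the spread of slopes, 172 were scored as unchanged. For counts of genes and lists this score followed the total called, not its direction or which members passed. Stable reference centring was so scored for slopes in vector uninduced cells, where 987 rose and 6201 fell against 5025 and 2444. The same score was given to levels in the Tob2 line, with 22 higher and 111 lower against 99 and 23. For named genes 17385 of 18447 values were scored as unchanged, with 436 weaker, 152 stronger, 447 moved and 27 reversed. With a pseudocount of 0.1 and with no filter the 14 and 13 values of the first kind were scored as unchanged. Levels then differed in 112 and 104 genes in the Tob2 line against 122. Without a filter they differed in 2 against 3 genes between uninduced lines, 1 of them shared. Using only the libraries of the arms compared gave no separate value for differences between the lines, which use all 4 arms. Single-gene calls near the threshold were lost mostly by fits with fewer libraries; otherwise the cause was not tested. What depth limits could not be stated, since depth was unknown.

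Over 0 to 2 h the genes with a slope numbered 2332 in vector uninduced, 1573 in vector induced, 2515 in Tob2 uninduced and 1589 in Tob2 induced cells, and those with a level difference 49 in the Tob2 line and 3 in the vector line. With chase time as a block 17 slopes differed in the Tob2 line and 1 between the lines' effects, and levels differed in 893, 112, 40 and 25 genes (Tob2 line, vector line, difference, uninduced lines). The level count in the Tob2 line was 63 after rescaling, 23 with the arms compared only (1 slope and 3 levels in the vector line), 20 for single transcripts (1 in the vector line, 0 between uninduced lines), 55 without the added library and 19 to 114 when 1 chase time was left out. Leaving out 1 chase time gave 3 to 9 levels in the vector line, 0 to 2 for the difference, 0 to 4 between uninduced lines, and 0 to 1 slopes in the Tob2 line and between uninduced lines; the TOB2 difference then ranged from 1.14 to 1.43, where 5 pairs cannot give an exact p under 0.05. Median centring gave 2 genes for the difference in level. The ratio of slope spreads was 0.9588 to 1 when 1 chase time was left out, reaching 1 without 0 h, and 0.9335 over 0 to 2 h.

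The list calls of the report rested on the preset correlation. With an estimated one, 0 lists passed for slopes in vector uninduced, Tob2 uninduced and Tob2 induced cells, 2 in vector induced cells, 0 for slope in the Tob2 line, 1 in the vector line, 1 for the difference and 0 between uninduced lines; for levels 2 passed in the Tob2 line and 0 in the vector line, for the difference and between uninduced lines. Median centring kept the direction of every list call but ended some of them, named in the report. For the difference in level 3 lists passed with median centring and 9 with chase time as a block, where 5 passed before.

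Slopes that reversed (log2 per h) were, in vector uninduced cells over 0 to 2 h, TOB1 0.0971, TOB2 0.0051, BTG1 0.44, DNAJB9 0.0524, CDKN1B 0.13, SMG8 0.19, IFIT2 0.31, ELF3 0.41, SNHG20 0.20, SNHG3 0.25, CYR61 0.12 and SMAD7 0.40, and with stable reference centring CNOT6L −0.0268, PAN3 −0.0261 and CCND1 −0.13 (−0.0769 rescaled). In vector induced cells they were CNOT6 (−0.0059 centred, −0.0354 over 0 to 2 h), CNOT6L −0.0299, PAN3 −0.0064 and CCND1 (−0.12 centred, −0.0677 rescaled). In Tob2 uninduced cells PAN3 had −0.0907 centred, and in Tob2 induced cells BTG1 had 0.28, CNOT6 −0.0178 and PAN3 −0.0085 over 0 to 2 h, and PAN3 −0.0201 centred. Stable reference centring moved all slopes of an arm by the same amount (−0.13 in vector uninduced cells). Of the reversed slopes, those of BTG1 (0.44) and ELF3 over 0 to 2 h in vector uninduced cells, of CCND1 in each case and of PAN3 in Tob2 uninduced cells passed. For the chase window and the rescaling the cause was not tested.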

Other observations

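The values in this part were picked out after the data were seen, and none was planned. Of the 1647 genes whose labelled RNA fell over the whole chase in all 4 arms, 107 had slopes above 0 over 0 to 2 h in all 4. Averaged over the arms, TXNIP, an inhibitor of thioredoxin, had 31.6 TPM at 0 h, 57.8 at 2 h and 7.29 at 6 h. SMAD7, an inhibitor of TGF-beta signalling, had 50.4 TPM at 0 h, 101.6 at 1 h and 10.1 at 6 h, and TRIB1 had 84.6, 199 and 3.05 TPM at these times. KLF4 went from 129 TPM at 0 h to 227 at 1 h and 63.0 at 6 h. A straight line over 6 h does not describe these genes.

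Of 22 cholesterol synthesis genes 5 had their lowest and 5 their highest mean level in Tob2 induced cells, and 16 were highest in Tob2 uninduced cells. INSIG1 and MSMO1, picked from these 22 and both targets of the sterol-regulated factors, had their lowest mean levels in Tob2 induced cells: 6.23, 6.42, 6.54 and 5.98 log2 for INSIG1 and 7.18, 7.39, 7.47 and 7.01 for MSMO1 in vector uninduced, vector induced, Tob2 uninduced and Tob2 induced cells. The Tob2 uninduced arm was the highest of the 4 for both, and the difference in level effect between the lines passed only with chase time as a block (INSIG1 −0.74, adjusted p = 0.018; MSMO1 −0.66, adjusted p = 0.0082, limma). Across 13275 genes, TOB2 left out, level differences on induction correlated weakly between the lines (r = 0.13, rho = 0.20) and slope differences hardly at all (r = −0.01, rho = 0.11); genes are not independent replicates.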
